A study of Mus musculus with 48 samples.

How the data were processed

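The deposited RNA-seq files held raw gene counts per symbol, which the authors had made from the sequencing reads, and no normalization had been applied to them per the file headers. The deposited RACE files listed genomic positions (mm9) with a signal whose values, as deposited by the authors, were reads per position divided by a constant of each library, as read from the values, which are whole multiples of a step. Dividing each value by the smallest of its library gave whole numbers for 100% of values within a tolerance of 0.02 (1e-05 of the value where that was larger), and these were used as read counts. The deposited small RNA files listed each distinct sequence with its read count, its genomic locations and their number, as counted by the authors per the file headers. Per the submitters' processing notes, Bowtie 1.0.0, STAR 2.3.1z12, HTSeq 0.6.1p1, DESeq 1.16.0 and the builds mm9 and hg19 were used, with no roles stated. A RACE file lists only positions with reads, and which positions were kept is not stated.

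RNA-seq genes were the 23926 symbols present in all 23 libraries. The 5 WT and Hu6 libraries of RS used a list of 23944 symbols and the other 18 libraries a list of 24001, and the 18 and 75 symbols found in one kind of list were left out. Genes were filtered with filterByExpr (minimum count 10, minimum total count 15), which left 16424, normalised with TMM and fitted with the quasi-likelihood method of edgeR 4.0.16 in R 4.3.3, with 1 coefficient per group over all 23 libraries. The common biological coefficient of variation was 0.241. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg within each contrast with a threshold of 0.05. The SE of a log2 fold change is its absolute value divided by the square root of the F statistic. The 11 contrasts were KO against Het and Het against WT at PY, SS and RS, Hu6 against WT in RS, SS against PY and RS against SS in WT, and the KO effect in RS and in SS minus that in PY. Het was the main control because the RACE libraries compare the same genotypes. Het and WT libraries differ in depth, so that genotype and library batch cannot be separated between them.

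The 15 gene lists were fixed before the data were examined: piRNA pathway, meiotic prophase, meiotic division, spermiogenesis, CREM and ACT targets, acrosome, post-meiotic sex-linked genes, DNA damage and apoptosis, RNA decay and translation, ribosomal proteins, and markers of spermatogonia, Sertoli, Leydig, peritubular and endothelial, and immune and blood cells. Lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01, with an estimated correlation, and with fry, over 165 pairs of list and contrast. Genes named in the text were chosen by a rule fixed at the same time. It took the 10 largest increases and decreases (5 for Het against WT and WT stages) among genes past the threshold with at least 5 CPM on average and no overlap between groups, up to 4 members of each list with the smallest adjusted p, and Piwil1, Dpy19l2, Piwil2 and Ddx4 always. For RACE it took the 10 positions with the smallest adjusted p per direction, and the 10 positions opposite a small RNA with the most Het reads. Libraries that did not overlap between groups were counted for each gene: 36.4% of genes in KO against Het PY, 68.6% in SS and 66.6% in RS (33.3% by chance), and 18.1% in Hu6 against WT (20% by chance). Current symbols covered 22784 of the shared symbols, and 1031 were found only as synonyms.

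RACE positions were tested with the same edgeR steps over 19 libraries. Of 95134 positions, 58692 had at least 10 reads, 14848 passed the filter, and 39631 of the 58692 shared their counts in every library with another position, as repeated alignments of the same reads do. No genome sequence was at hand, so positions were not assigned to genes, and repeated sequence was not masked. For the offset search, each RACE position was compared with 5′ ends of small RNAs of both WT MIWI immunoprecipitates on the other strand at 1 to 20 nt. The ratio of the 10 nt share to the mean of the other offsets was compared between KO and Het by a two-sided exact permutation within stages. Small RNAs on human chromosome 6 were counted in RPM, reads scaled to those mapped to hg19, each sequence once in the region, with 95% Wilson intervals. In bins and windows, a read was divided by its number of locations. The 1 WT immunoprecipitate without a file for hg19 was left out of that count.

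The steps were checked and tested on simulated data. With planted changes of log2 1, 2 and 3, edgeR recovered 19.4%, 95.5% and 100% in KO against Het RS, 25.4%, 100% and 100% in Hu6 against WT, and 38.8%, 100% and 100% in SS against PY of WT. Changes were planted in 67, 67 and 66 genes, with 1 common spread for all genes. Unchanged genes were called 1, 11 and 3 times in the 3 comparisons. The offset search found a planted 10 nt offset among 20000 positions. For RACE, no planted change of log2 3 or 6 was recovered at the spread estimated from the libraries (common biological coefficient of variation 2.17), while at a dispersion of 0.2, 87% and 100% were recovered in KO against Het RS. A small number of RACE calls therefore does not show that few positions changed. Duplicated libraries were looked for and none were found, with a lowest chi-square per degree of freedom of 7.62 over 16 RNA-seq pairs and 77.6 over 15 RACE pairs.

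The alternatives were RLE size factors, no filter, DESeq2 1.42.0, only the compared groups, a replicate block, a threshold of 0.01, other controls, and each library left out. Added after the data were seen were counts thinned to the smallest library, fits without WT 2 and KO 2 of PY, 1 position per identical count pattern, positions listed in both groups, small RNAs with 1 mouse locus, and a replicate block within Het and KO for the differences between stages. Figures and small RNA counts used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.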

Results

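The 48 libraries came from sorted mouse spermatogenic cells and whole testes. RNA-seq covered 23 libraries of pachytene spermatocytes (PY), secondary spermatocytes (SS) and round spermatids (RS). Each stage had 3 wild-type libraries (WT, MW+/+), 2 heterozygous libraries (Het, MW+/-) and 2 knockout libraries (KO, MW-/-) for MIWI, the PIWI protein encoded by Piwil1 that binds pachytene piRNAs. A further 2 RNA-seq libraries came from RS of Hu6 mice, which carry a human bacterial artificial chromosome. The 19 libraries of 5′ RACE, which records the 5′ ends of RNA fragments, held 2 Het and 2 KO libraries per stage, 4 WT RS libraries and 3 Hu6 RS libraries. The 6 small RNA libraries of whole testes were 3 MIWI immunoprecipitates (2 WT, 1 Hu6) and 3 total small RNA libraries (1 each of WT, Hu6 and a genotype labelled Hu6 delta). RNA-seq libraries held 5790602 to 19302873 counted reads, and every WT and Hu6 library was smaller than every Het and KO library. RACE libraries held 1553168 to 19987772 reads at 5139 to 21195 positions. Fold changes are log2 values with their standard error (SE), levels are counts scaled to library size (CPM) with the SD between libraries, and p-values are adjusted for the false discovery rate unless stated. For RNA-seq they measure only the spread between these libraries, which may be technical as well as biological. For RACE the prior degrees of freedom were infinite, so p-values came from a spread modelled over all positions, not from a position's own.

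Piwil1, the targeted gene, was measured first. In PY it stood at 467, 498.1 and 886.5 CPM in the WT libraries, 333.4 and 377 CPM in the Het libraries, and 74.98 and 63.82 CPM in the KO libraries. In SS it stood at 58.73, 84.34 and 43.5 CPM in WT, 74.27 and 70.55 CPM in Het, and 54.76 and 50.14 CPM in KO. In RS it stood at 51.42, 51.23 and 61.38 CPM in WT, 86.26 and 95.33 CPM in Het, 59.43 and 52.86 CPM in KO, and 70.65 and 56.39 CPM in Hu6. Piwil1 mRNA fell in KO PY against Het PY by 2.36 ± 0.29 on the log2 scale (adjusted p = 0.000415). The KO and Het libraries were not told apart for Piwil1 in SS (log2 -0.47 ± 0.28, adjusted p = 0.358) or in RS (-0.69 ± 0.28, adjusted p = 0.124). The KO effect on Piwil1 itself did not pass the test of a difference between RS and PY (1.66 ± 0.40, adjusted p = 0.06) or between SS and PY (1.89 ± 0.40, adjusted p = 0.0833).

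In KO PY, the stage at which pachytene piRNAs appear, few mRNAs differed from Het (2 libraries against 2). Stambp, an endosomal deubiquitinase, rose by 3.15 ± 0.27, from 34.13 ± 5.38 to 304.1 ± 9.71 CPM (adjusted p = 8.02e-06). Ptchd3 rose by 2.10 ± 0.19 to 724.5 ± 41.2 CPM, Prelid1, a mitochondrial lipid transfer protein, by 2.55 ± 0.31, and Clmp, a cell adhesion molecule, by 2.77 ± 0.52. Aen (1.81 ± 0.35), Scpep1 (1.51 ± 0.22) and Golga2 (1.44 ± 0.24), which encodes a Golgi matrix protein, rose as well, as did the uncertain symbols Gm595 (2.18), LOC666331 (1.71) and Zfa-ps (1.6), which stand for predicted or multi-copy genes. Antxr2, an anthrax toxin receptor, fell by 2.68 ± 0.29 and Fam69a by 1.97 ± 0.39, beside the uncertain symbols 2010109A12Rik (-4.81), 4930503B20Rik (-3.55) and Gm21269 (-1.31). Among piRNA pathway genes, Tdrd1, a tudor domain protein that binds PIWI proteins, rose by 1.14 ± 0.23 (adjusted p = 0.0442), and Piwil2 stood at 0.62 ± 0.24 (adjusted p = 0.608) and the helicase gene Ddx4 at -0.09 ± 0.19 (adjusted p = 1). In all, 29 genes were higher and 15 lower in KO PY of 16424 tested. The count was 8 (3 up, 5 down), 9 (4 up, 5 down), 17 and 15 without Het 1, Het 2, KO 1 and KO 2, so that the balance turned without either Het library. It also turned against WT (1568 up, 2200 down) and against the mean of WT and Het (408 up, 681 down). It was 144 with DESeq2 and 69 when the compared groups were fitted alone. It was 72 without WT 2, which lay apart from the other WT libraries, and KO 2, which held 21168 reads of the ribosomal RNA symbol Rn45s against 5610 in KO 1.

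In KO SS, 638 genes were higher and 413 lower than in Het. Tex101, a germ cell surface protein, rose by 5.79 ± 0.51, from 6.286 ± 0.854 to 348.9 ± 4.17 CPM (adjusted p = 2.32e-06). Prelid1 (3.92 ± 0.34) and Stambp (3.58 ± 0.28) rose again, with Ceacam20 (4.54 ± 0.71), Asprv1 (4.19 ± 0.64), the hormone precursor gene Trh (3.79 ± 0.43), Tapbpl (3.63 ± 0.43), AY358078 (3.56 ± 0.47), Lrrc4c (3.56 ± 0.50) and Morc1 (3.56 ± 0.38). Among the genes that fell were Chrna5, a nicotinic receptor subunit (-3.29 ± 0.50, adjusted p = 0.000552), and Prss51, a serine protease gene (-3.21 ± 0.57, adjusted p = 0.00207). The other large decreases carried uncertain symbols, among them 4930519F24Rik (-5.75), 2010109A12Rik (-5.74), 1700029B22Rik (-3.85), 1700012A03Rik (-3.55), 4933402N03Rik (-3.52), Gm6432 (-3.45), Gm136 (-3.37) and 1700061I17Rik (-3.25). Tdrd1 rose by 2.77 ± 0.25 in KO SS (adjusted p = 2.44e-06), and Mybl1, a transcription factor of pachytene piRNA genes, fell by 0.89 ± 0.21. The protamine and transition protein mRNAs Prm1 (-2.79 ± 0.68), Prm2 (-2.96 ± 0.79), Tnp1 (-2.23 ± 0.60) and Tnp2 (-2.56 ± 0.61) were lower. The SS total of 1051 was 243, 256, 256 and 382 without Het 1, Het 2, KO 1 and KO 2, 1741 with DESeq2, 4905 with the compared groups alone (2351 up, 2554 down) and 534 with counts thinned to the smallest library.

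In KO RS, 941 genes were higher and 1022 lower than in Het. Prelid1 rose by 5.29 ± 0.37, from 1.487 ± 0.355 to 58.71 ± 1.5 CPM (adjusted p = 1.29e-07), Tex101 by 5.16 ± 0.50 to 425.8 ± 1.35 CPM, and Stambp by 4.89 ± 0.30 to 149 ± 40.7 CPM. Asprv1 (4.42 ± 0.63), Ccndbp1 (4.26 ± 0.47), Zfp334 (4.18 ± 0.66), Ceacam20 (3.94 ± 0.66), the mitochondrial protein genes Fastkd1 (3.93 ± 0.31) and Mtg2 (3.81 ± 0.38), and the uncertain symbol 4930539N22Rik (4.92) also rose. Tdrd1 reached 697.1 ± 20.6 CPM against 92.39 ± 3.52 CPM in Het (2.92 ± 0.25, adjusted p = 8.13e-07), and Piwil2, which encodes the PIWI protein MILI, rose by 1.29 ± 0.24 (adjusted p = 0.00144). Prm1 fell by 4.35 ± 0.73, from 3533 ± 39.9 to 172.8 ± 13.4 CPM (adjusted p = 0.000548), as did Tnp2 (-3.88 ± 0.64), Prm2 (-4.43 ± 0.85), Tnp1 (-3.32 ± 0.63) and Tssk6, a kinase of late spermatids (-3.41 ± 0.56). Among decreases with uncertain symbols, 4933406G16Rik had no read in KO and was at least 183-fold lower, against a floor of 3 counts over the group. 4930432J09Rik (-7.37), 4930519F24Rik (-7.30), 2010109A12Rik (-5.82), 4933402N03Rik (-5.39), 1700029B22Rik (-5.26), Klk1b8 (-4.84), Gm136 (-4.77), 1700012A03Rik (-4.73) and 1700080E11Rik (-4.70) fell too. The RS total of 1963 was 767, 907, 773 and 797 without Het 1, Het 2, KO 1 and KO 2, 6085 with the compared groups alone and 1284 with thinned counts. Increases outnumbered decreases without Het 1 (390 and 377), KO 1 (464 and 309) and KO 2 (513 and 284), with the compared groups alone (3145 and 2940), at a threshold of 0.01 (505 and 442), against WT (2950 and 2053) and against the mean of WT and Het (2353 and 1834).

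**Figure D1:**
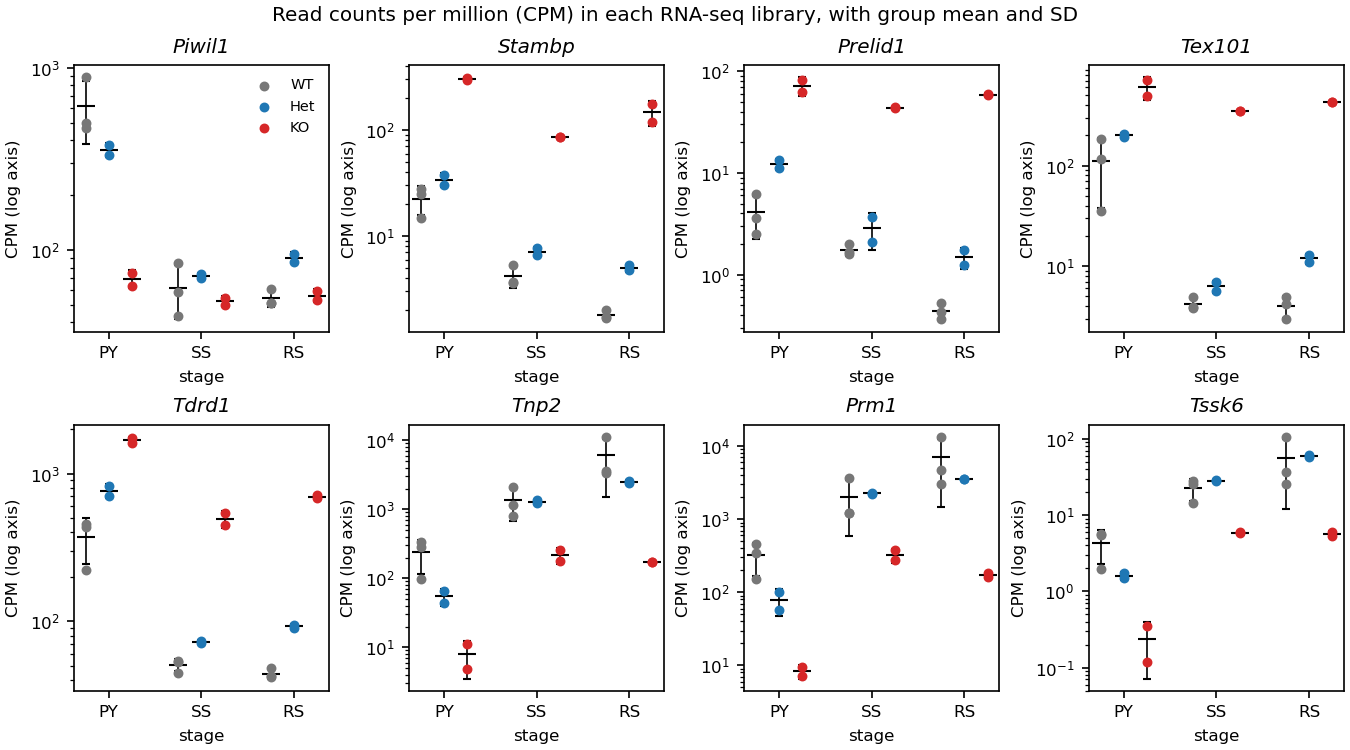
CPM (log axis) of 8 genes in each WT, Het and KO library of PY, SS and RS, with the group mean and SD. Among the libraries of PY, Piwil1 is lowest in those of KO, and the KO libraries of RS sit at 58.71 CPM for Prelid1 and 172.8 CPM for Prm1 on average.

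Genes called at one stage were often called at another, with chance figures that treat the stages as independent. The KO increases of PY and SS shared 23 genes (1.13 by chance), those of PY and RS 25 (1.66 by chance) and those of SS and RS 438 (36.6 by chance). The decreases of SS and RS shared 278 genes (25.7 by chance), and in no pair of stages was a gene higher in one and lower in the other. A test of the difference between stages passed for 122 genes between RS and PY, with 99 more positive and 23 more negative in RS, and for 20 genes between SS and PY, with 16 more positive and 4 more negative in SS. For Tex101 the KO effect was larger in RS than in PY by 3.57 ± 0.61 (adjusted p = 0.00824) and larger in SS than in PY by 4.20 ± 0.62 (adjusted p = 0.00734). It was larger in RS than in PY for Tdrd1 (1.78 ± 0.33, adjusted p = 0.015), Brca2 (2.02 ± 0.40, adjusted p = 0.0203), Atr (1.65 ± 0.32, adjusted p = 0.0157) and Rpl14 (1.95 ± 0.40, adjusted p = 0.0276). The genes Gnl2 (2.42), Fastkd1 (3.18), Mtg2 (2.81), Prelid1 (2.74) and Fam196b (-5.12) in RS, and Ctnna2 (2.61), Fastkd1 (2.50), Antxr2 (1.93), Fam196b (-8.33), Ptchd3 (-1.83), Ccdc117 (-1.78) and Tmem194 (-1.66) in SS, were chosen after their values were seen. With replicate number as a block within Het and KO, the counts were 70 between RS and PY and 15 between SS and PY. The RS count was 36, 22, 54 and 33 without PY Het 1, Het 2, KO 1 and KO 2, and 22, 25, 22 and 35 without RS Het 1, Het 2, KO 1 and KO 2. The SS count was 3, 7, 10 and 0 without the same PY libraries, and 4, 8, 5 and 13 without SS Het 1, Het 2, KO 1 and KO 2.

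Genes of spermatid differentiation were examined as lists. Of 54 spermiogenesis genes tested in RS, 19 fell, 1 rose and 34 did not pass (33 down and 1 up adjusted over the list alone), with a median of -0.73. The set test gave an adjusted p = 2.71e-12, and an adjusted p = 0.315 with an estimated correlation. The gene that rose was Pick1 (0.67), outside the naming rule and chosen after its value was seen. The targets of the transcription factor CREM and its partner ACT, which share members with that list, gave 10 decreases among 24 genes (15 adjusted over the list alone) and a median of -0.76 (adjusted p = 2.57e-07, adjusted p = 0.315 with an estimated correlation). Of 37 acrosome genes in RS, Hspa1l (-2.16 ± 0.46), Actl9 (-1.24 ± 0.33) and Spaca4 (-0.79 ± 0.24) fell and none rose, the same 3 adjusted over the list alone (set adjusted p = 0.000815, adjusted p = 0.512 with an estimated correlation). Of 19 post-meiotic sex-linked genes, Akap4, a sperm tail scaffold protein (-1.47 ± 0.42), and the uncertain multi-copy symbols Cypt12 (-1.6) and Ssxb3 (-1.71) fell in RS. In SS, Tmem95 of the acrosome list (1.39) and Zfy2 of the sex-linked list (1.51) rose, with 0 and 5 increases adjusted over the lists alone. In SS, 5 of the 54 spermiogenesis genes fell (11 down and 1 up adjusted over the list alone), Tssk6 (-2.27 ± 0.53) beside the protamines and transition proteins, with a median of -0.35 (adjusted p = 8.95e-06, adjusted p = 0.656 with an estimated correlation). Beside these decreases, the medians of the Leydig and the peritubular and endothelial markers were 0.94 and 0.51 in RS and 0.43 and 0.93 in SS. In PY no member passed over all genes, and 13 were lower adjusted over the list alone. The median was -0.53 (adjusted p = 1.11e-22, adjusted p = 0.0501 with an estimated correlation), and Prm1 stood at -3.25 ± 0.71 (adjusted p = 0.0674) and Tnp2 at -2.78 ± 0.63 (adjusted p = 0.0879). In PY the medians of the peritubular and endothelial and the immune markers were 0.84 and 1.21, and that of the Leydig markers was -0.18.

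Other gene groups held members that moved both ways in KO cells. Of 29 DNA damage and apoptosis genes in RS, the kinase genes Atr (1.83 ± 0.23) and Chek2 (2.97 ± 0.69), Gadd45b (2.97 ± 0.54) and Pmaip1 (2.52 ± 0.59) rose and Tnfrsf10b (-1.43, chosen after its value was seen) fell. The count was 5 up and 1 down adjusted over the list alone, with a set adjusted p = 0.0283 that became adjusted p = 0.96 with an estimated correlation. In SS, Atr (0.88 ± 0.22), Bcl2l11 (1.65 ± 0.46) and Gadd45b (1.59 ± 0.46) rose (adjusted p = 0.0922 for the set). Of 25 piRNA pathway genes in RS, Tdrd1, Piwil2 and the helicase gene Tdrd9 (0.82 ± 0.19) rose (adjusted p = 0.437 for the set, with a median of -0.01 and a mean of 0.16). In PY the median of that list was 0.06, its mean -0.02 and its test pointed down, and in SS they were -0.10 and 0.01. Of 36 meiotic prophase genes, the recombination gene Brca2 rose in RS (2.34 ± 0.29) and in SS (1.04 ± 0.28) beside Tex101, while Mlh3 (-0.71 ± 0.19) and Cntd1 (-0.67 ± 0.18) fell in SS. Of 29 meiotic division genes, Ube2c rose in both stages (2.02 ± 0.32 in SS, 1.89 ± 0.31 in RS), Ccnb3 (1.79 ± 0.50) and Ttk (0.66 ± 0.21) rose in RS, and Bub1b (-0.89 ± 0.21) and Cdk1 (-0.99 ± 0.25) fell in SS, where the set had an adjusted p = 0.00621 (adjusted p = 0.68 with an estimated correlation). Of 40 RNA decay and translation genes in RS, Ago2 (1.6 ± 0.27), Cnot8 (2.22 ± 0.43) and Xrn1 (1.02 ± 0.20) rose and Ddx6 (-0.64 ± 0.18) fell, with Parn (-1.28), Upf2 (-0.62) and Eif4e (-0.65) chosen after their values were seen. The median of that list was -0.11 and its mean 0.08. In SS, Ddx6 (-0.82 ± 0.18), Upf2 (-0.68 ± 0.18) and Khdrbs1 (-0.71 ± 0.20) fell. The decreases of Ddx6 in RS and of Mlh3 and Khdrbs1 in SS had the other sign against WT (0.33, 0.17 and 0.02). The decrease of Eif4e in RS had the other sign against WT as well (0.3). Of 39 ribosomal protein genes, whose symbols share reads with pseudogenes, Rpl14, Rpl10a, Rps3, Rpl4 and Rps5 rose in both stages and Rplp0 fell, with Rplp0 in both stages, Rpl4 in SS and Rps5 in RS chosen after their values were seen. Rplp0 in SS had the other sign against WT (0.3). In RS the ribosomal median was -0.01 and its mean 0.17. In SS the set had a median of 0.32 and an adjusted p = 0.00621 (adjusted p = 0.656 with an estimated correlation).

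Few markers of other testis cells passed in the KO comparison, while several list medians were positive. In RS the spermatogonial marker Lin28a rose (3.73 ± 0.88) and Sohlh1 fell (-4.54 ± 1.35), the Sertoli marker Ar rose (1.47 ± 0.45), the Leydig marker Scarb1 fell (-0.90 ± 0.28), and the immune marker C1qb fell (-3.36 ± 0.95). Of 20 peritubular and endothelial markers in RS, Acta2 (2.84 ± 0.84) and Cdh5 (2.22 ± 0.68) rose and Actg2 fell (-2.71 ± 0.36). Actg2 fell in PY (-2.18 ± 0.44) and SS (-1.86 ± 0.35) as well. In RS the medians were 0.94 for the Leydig list, 0.51 for the peritubular and endothelial list and 0.27 for the immune list (set adjusted p = 0.464, 0.933 and 0.981). In SS they were 0.43, 0.93 and 0.56 (set adjusted p = 0.99, 0.267 and 0.669). In PY the medians of the peritubular and endothelial list (0.84) and of the immune list (1.21) were positive, with set adjusted p = 0.0286 and 0.0131 (adjusted p = 0.667 for each with an estimated correlation). The spermatogonial list (median 0.34, adjusted p = 0.0291) and the meiotic prophase list (median 0.15, adjusted p = 0.041) behaved alike, again with adjusted p = 0.667 with an estimated correlation.

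**Figure D2:**
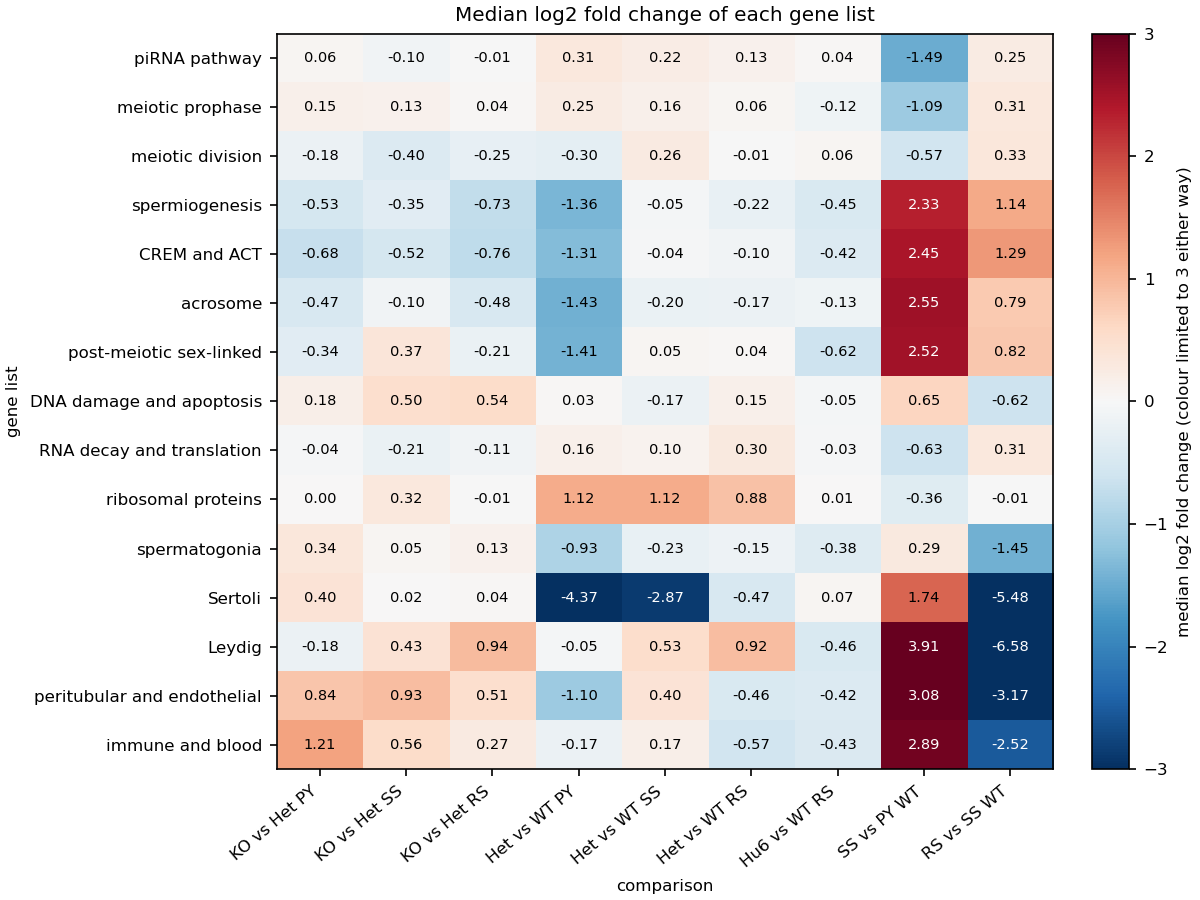
Median log2 fold change of each gene list (vertical axis) in each comparison (horizontal axis), with the value printed in the cell and the colour limited to 3 either way. The spermiogenesis list has medians of -0.53, -0.35 and -0.73 in KO against Het, and the ribosomal list 1.12, 1.12 and 0.88 in Het against WT.

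The Het and WT libraries, the 2 kinds of control, differed at every stage. Of 39 ribosomal protein genes, 20 rose and 1 fell in Het PY, 20 rose in Het SS and 19 in Het RS (24, 23 and 22 up and 1 down at each stage adjusted over the list alone), with medians of 1.12, 1.12 and 0.88. These sets passed with the preset correlation (adjusted p = 2.43e-31, 1.29e-37 and 1.85e-24) and with an estimated correlation (adjusted p = 0.000518, 8e-05 and 0.00183). Rpl7 rose by 3.60 ± 0.22 in PY, 3.07 ± 0.22 in SS and 2.83 ± 0.22 in RS, and Rps7 by 3.29 ± 0.25, 3.33 ± 0.25 and 3.30 ± 0.25, both symbols with pseudogene copies. Increases with uncertain symbols included Rnu12 (6.71 in PY, 7.45 in SS, 7.26 in RS), Rps17 (6.45, 6.79 and 5.02) and Scarna10 (5.52, 5.38 and 4.88). Gm6402 (4.90 in PY, 4.50 in SS), 4933406F09Rik (6.34 in SS, 5.90 in RS), Nsa2 in PY (4.27 ± 0.36) and Naa38 in RS (4.01 ± 0.20) also rose. Dynlt1b fell (-5.76 ± 0.43 in PY, -5.47 ± 0.43 in SS and -5.78 ± 0.43 in RS), from 200 ± 69.4 to 3.693 ± 0.215 CPM in PY, and belongs to a family of near-identical genes. The uncertain symbols Gm13315 (-4.58 in SS, -5.36 in RS), 1810009A15Rik (-4.16 in SS, -4.47 in RS), Gm15070 in PY (-6.30), Snord34 in SS (-4.84) and E130201H02Rik in RS (-4.02), and AU015836 in SS (-4.25 ± 1.02), fell too. The symbol 2310044G17Rik had no read in any of the 18 libraries counted with the longer gene list, so its RS difference followed the gene list used.

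Acrosome and Sertoli genes were lower in Het PY than in WT PY when all libraries were fitted. Of 37 acrosome genes, 23 fell in Het PY (27 adjusted over the list alone), among them Fam170b (-1.62 ± 0.26), Tmem190 (-1.90 ± 0.32) and Actl7a (-1.64 ± 0.28), with a median of -1.43 (adjusted p = 1.44e-11, adjusted p = 0.0487 with an estimated correlation). Of 22 Sertoli markers, 17 fell in Het PY (20 adjusted over the list alone), with a median of -4.37 (adjusted p = 9.65e-07, adjusted p = 0.475 with an estimated correlation). Wt1 (-5.53 ± 1.20), Aard (-5.17 ± 1.19), Cst9 (-5.77 ± 1.33) and Cldn11 (-5.26 ± 1.23) were among them, as were Qpct (-5.81 ± 1.40) and Nxf3 (-5.63 ± 1.26) outside the list. In SS, Wt1, Inhbb, Espn, Dhh and Tsx, the last chosen after its value was seen, fell (17 adjusted over the list alone), with a median of -2.87 (adjusted p = 2.57e-10, adjusted p = 0.608 with an estimated correlation). Of 54 spermiogenesis genes, 28 fell in Het PY (36 down and 1 up adjusted over the list alone), with adjusted p = 1.72e-12 and adjusted p = 0.171 with an estimated correlation. These decreases in PY rested in part on WT 2, which lay at -0.521 on the second scaling dimension against 1.804 and 2.505 for WT 1 and WT 3. Without WT 2, 21 acrosome genes, 6 Sertoli markers and 30 spermiogenesis genes fell in Het PY, with medians of -0.85, -1.71 and -0.95. The counts were 13, 1 and 17 without Het 1 and 3, 0 and 2 without Het 2, and with the compared groups alone none of the 3 lists had a decrease that passed. The ribosomal list had 21 increases without WT 2, 18 without Het 1, 17 without Het 2, and 4 of 35 genes with the compared groups alone. The kinase gene Atr rose in Het at each stage (0.65 ± 0.20, 0.87 ± 0.20 and 0.72 ± 0.20), as did the translation factor gene Eif4e (1.23 ± 0.18, 1.35 ± 0.18 and 0.95 ± 0.18). In total, Het PY had 980 genes up and 1741 down, Het SS 705 and 310, and Het RS 718 and 76. With RLE size factors the share that rose moved from 36% to 25.7% in PY and from 69.5% to 55.9% in SS, and the median of all genes moved from -0.0686 to -0.172 in PY, from 0.0283 to -0.0715 in SS and from 0.105 to 0 in RS. The balance in PY turned without WT 2 (1962 up, 1474 down), without Het 2 (224 up, 111 down) and with the compared groups alone (29 up, 5 down). That in SS turned with DESeq2 (751 up, 843 down) and with the compared groups alone (628 up, 981 down), while increases stayed in excess in RS (725 and 345, 516 and 288). The PY total of 2721 was 976 without Het 1, 335 without Het 2 and 34 with the compared groups alone. The SS total of 1015 was 466 and 562 without WT 1 and WT 3 and 241 and 260 without Het 1 and Het 2, and the RS total of 794 was 489 and 510 without WT 1 and WT 2 and 363 and 262 without Het 1 and Het 2.

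Between PY and SS of WT mice, piRNA pathway mRNAs fell and mRNAs of later differentiation rose. Piwil1 fell by 3.31 ± 0.25 (adjusted p = 1.69e-08), Piwil2 by 2.61 ± 0.21, Tdrd1 by 2.87 ± 0.21 and Tdrd5 by 3.29 ± 0.20. Of 25 piRNA pathway genes, 18 fell, and Kif17 (2.11 ± 0.21) rose with Tex15 (2.04) and Gtsf1 (0.57), chosen after their values were seen, with the same counts adjusted over the list alone (adjusted p = 1.63e-07, adjusted p = 0.115 with an estimated correlation). Of 36 meiotic prophase genes, 25 fell, such as Tex101 (-4.72 ± 0.42) and Mlh3 (-1.93 ± 0.16), and the cohesin gene Rec8 (2.72 ± 0.26) rose with Syce2 (1.27) and Syce3 (0.68), chosen after their values were seen (set adjusted p = 3.64e-05, adjusted p = 0.23 with an estimated correlation). The DNA damage histone gene H2afx fell by 4.20 ± 0.22 and Atr by 2.28 ± 0.19. Of 54 spermiogenesis genes, 37 rose, such as the sperm calcium channel gene Catsper4 (2.89 ± 0.27) and Odf3 (2.72 ± 0.25), and Gopc, Pick1, Spag6, Ldhc and Pgam2, chosen after their values were seen, fell (set adjusted p = 1.63e-07, adjusted p = 0.23 with an estimated correlation). Of 37 acrosome genes, 25 rose, such as Spaca4 (2.78 ± 0.22), while Dpy19l2 (-0.50 ± 0.16) fell with Adam2, Spata16, Spink2 and Pcsk4, chosen after their values were seen (set adjusted p = 1.63e-07, adjusted p = 0.115 with an estimated correlation). Of 19 post-meiotic sex-linked genes, 15 rose, such as Tsga8 (2.51 ± 0.29), and none fell (adjusted p = 1.12e-05, adjusted p = 0.23 with an estimated correlation). Markers of other cell types rose with them. All 15 Leydig markers rose (median 3.91, adjusted p = 0.000307, adjusted p = 0.341 with an estimated correlation), with the hormone gene Insl3 (5.29 ± 0.80) and the steroid enzyme genes Hsd3b1 (4.72 ± 0.78) and Hsd17b3 (4.58 ± 0.79), as did 17 of 20 peritubular and endothelial, 11 of 22 Sertoli (8 adjusted over the list alone) and 9 of 16 immune markers. Lcn2 (4.61 ± 0.74) and Ephx1 (4.51 ± 0.65) rose as well, and the uncertain histone symbols Hist1h2ba (-5.98) and Hist1h1t (-5.57), Ccnb1ip1 (-5.84 ± 0.67), a meiotic crossover gene, and the uncertain Gm21221 (-5.27) and Mir7230 (-4.89) fell. Of 40 RNA decay genes 25 fell, such as the decay factor gene Upf1 (-3.13 ± 0.27), and Parn, Upf3b, Eif4g1 and Xrn2, chosen after their values were seen, rose (adjusted p = 0.000781, adjusted p = 0.23 with an estimated correlation). Of 29 meiotic division genes 13 fell (12 adjusted over the list alone), such as Cks2 (-3.25 ± 0.29), and Cdc25c rose with Ccnb1 and Cdc25a, chosen after their values were seen. In total there were 5741 genes up and 4989 down, and RLE size factors moved the median of all genes from 0.158 to 0.305.

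Between SS and RS of WT mice, spermatid genes rose further and somatic markers fell. Of 54 spermiogenesis genes, 50 rose and Gopc (-0.67, chosen after its value was seen) fell, with a median of 1.14 (adjusted p = 1.35e-13, adjusted p = 0.222 with an estimated correlation). Prm2 rose by 2.47 ± 0.63, Odf2, an outer dense fibre protein, by 1.47 ± 0.21 and Tcp11 by 1.31 ± 0.19. Of 37 acrosome genes 27 rose and none fell (32 adjusted over the list alone), such as Fam170b (1.61 ± 0.21), and of 24 CREM and ACT genes 19 rose, such as the kinesin gene Kif17 (1.73 ± 0.20), and the multi-copy Klk1b24 (-6.13), chosen after its value was seen, fell. Odf3b (2.41 ± 0.61), the carbonic anhydrase gene Car2 (2.36 ± 0.57) and the uncertain 4933402P03Rik (2.25) rose as well. All 22 Sertoli markers fell (median -5.48), with Gata4 at least 53.4-fold lower and Sox9 at -7.21 ± 1.21. Of 15 Leydig markers 14 fell (median -6.58), such as Cyp11a1 (-7.60 ± 0.95), of 20 peritubular and endothelial markers 13 fell and Actg2 (1.28) and Kdr (1.05), chosen after their values were seen, rose, of 16 immune markers 8 fell, and of 16 spermatogonial markers 6 fell. Tmem35 (at least 86.2-fold lower), Trib2 (at least 85.1-fold lower), Igfbp6 (-8.36 ± 0.74), Sod3 (-8.05 ± 1.18) and Gja6 (-7.69 ± 1.37) fell as well. Of 29 DNA damage genes 12 fell, such as Sesn2 (-2.73 ± 0.36), and Mdm2 (0.71) and Mdc1 (0.62), chosen after their values were seen, rose (adjusted p = 0.0485, adjusted p = 0.546 with an estimated correlation). Piwil1 stood at -0.18 ± 0.23 (adjusted p = 0.529) and Piwil2 at -0.47 ± 0.20 (adjusted p = 0.0603). The totals were 3956 up and 4088 down, and RLE size factors moved the median of all genes from 0.101 to -0.00373.

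Hu6 mice address whether human piRNAs made in mouse cells act on mouse mRNAs. In Hu6 RS, 6 of 16424 genes differed from WT RS (2 libraries against 3). Dpy19l2, which encodes a protein needed to attach the acrosome to the nucleus, fell by 3.07 ± 0.20, from 655.7 ± 105 to 78.31 ± 9.64 CPM (adjusted p = 1.1e-07). Dad1, a subunit of the oligosaccharyltransferase, fell by 2.42 ± 0.21 (13.95 ± 2.40 against 74.71 ± 11.8 CPM, adjusted p = 3.13e-06), and Bbs5, a part of the BBSome of cilia, fell by 1.84 ± 0.25 (adjusted p = 0.00238). The uncertain symbol Gm11837 fell by 2.50 ± 0.22, and Necab1, which lies beside it and was chosen after its value was seen, by 2.58 (adjusted p = 0.0387). Slc41a1, a magnesium transporter, rose by 1.62 ± 0.23 (adjusted p = 0.00404). Piwil1 (0.22 ± 0.26), Piwil2 (0.16 ± 0.22) and Ddx4 (0.17 ± 0.17) did not pass. Dpy19l2 was not told apart between KO and Het RS (-0.22 ± 0.19, adjusted p = 0.566). No other member of the 15 lists passed besides Dpy19l2 of the acrosome list, also adjusted over the list alone. The set medians were negative for spermiogenesis (-0.45, adjusted p = 1.06e-13, adjusted p = 0.299 with an estimated correlation), CREM and ACT (-0.42, adjusted p = 5.39e-07, adjusted p = 0.299 with an estimated correlation) and sex-linked genes (-0.62, adjusted p = 7.52e-05, adjusted p = 0.618 with an estimated correlation). Tnp1 was at 2167 ± 584 CPM in Hu6 and 6242 ± 4470 CPM in WT, a spread that covered the difference. The total was 3 without Hu6 1, 3 without Hu6 2, 3 with the compared groups alone and 11 with DESeq2.

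**Figure D3:**
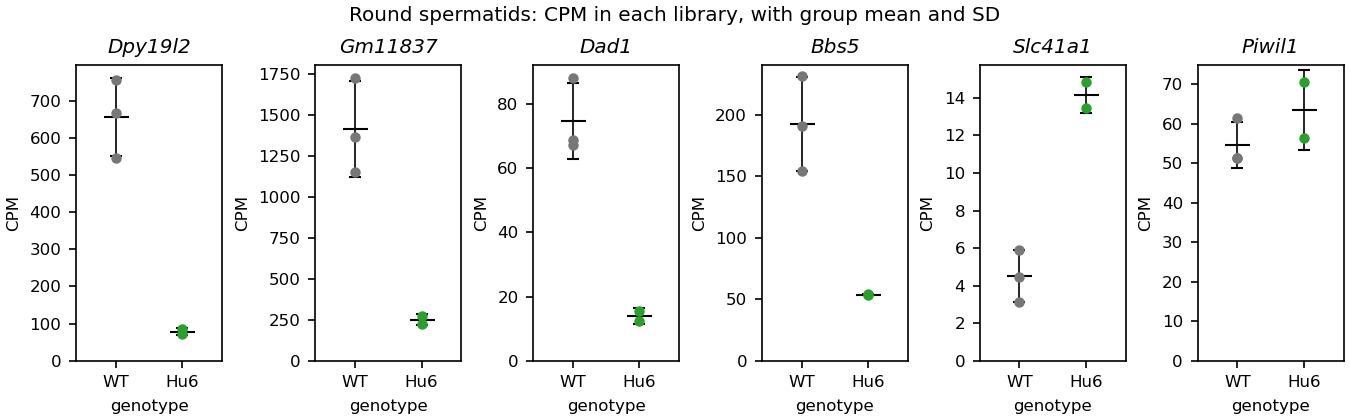
CPM of 6 genes in each WT and Hu6 library of RS, with the group mean and SD on axes from 0. Both Hu6 libraries lie below all 3 WT libraries for Dpy19l2, Gm11837, Dad1 and Bbs5, and above them for Slc41a1.

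Small RNA reads of Hu6 testes mapped to a region of human chromosome 6 (hg19, 33090001 to 33960000) far above WT. The region was set by the window of hg19 with the largest excess of Hu6 over WT in total small RNA. It was trimmed to the outermost bins where Hu6 far exceeded WT. The excess over WT in total small RNA was therefore fixed by that choice, which did not use the immunoprecipitates or Hu6 delta. Levels in the region are reads scaled to those mapped to hg19 (RPM), not to all mapped reads. In the WT 2 immunoprecipitate, 6979260 reads mapped to hg19 and 64525054 to mm9, so RPM values are not shares of all small RNA. In total small RNA, Hu6 had 29520 RPM in the region (95% Wilson interval 29200 to 29850), WT 2081 (1998 to 2168) and Hu6 delta 2240 (2187 to 2294). In MIWI immunoprecipitates, Hu6 had 182500 RPM (182100 to 182800) and WT 2 had 10800 (10730 to 10880). These are single libraries, and intervals and floors cover counting error only, since amplified reads are not independent molecules. The signal sat in 7 adjoining bins, from 33830001 to 33900000, which carried 97.2% of the region's Hu6 total small RNA and 97.9% of its Hu6 immunoprecipitate. These bins and the strand boundary below were chosen from the Hu6 total profile after it was seen. The bins carried 94.7% of the region in the WT 2 immunoprecipitate, 77% in WT total and 78.7% in Hu6 delta. On the plus strand, 97.9% of the Hu6 total reads of the region lay above position 33860000, and on the minus strand 91.1% lay below it, so that the strands pointed away from each other. The same shares were 94.8% and 99.2% in the WT 2 immunoprecipitate, 69.2% and 99.2% in WT total and 71% and 98.7% in Hu6 delta, so the pattern was not particular to Hu6. Of the Hu6 immunoprecipitate reads with 1 human locus and 24 to 33 nt, 88.9% (88.9 to 89.0) began with T, the DNA letter for the U that piRNAs carry at the 5′ end, and the most common length was 30 nt. The share that began with T was 93.6% (93.2 to 94.0) in Hu6 total small RNA, and higher in the WT 2 immunoprecipitate (96.1%, 95.9 to 96.3), WT total (97.2%, 95.5 to 98.3) and Hu6 delta total small RNA (97.6%, 96.8 to 98.2).

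**Figure D4:**
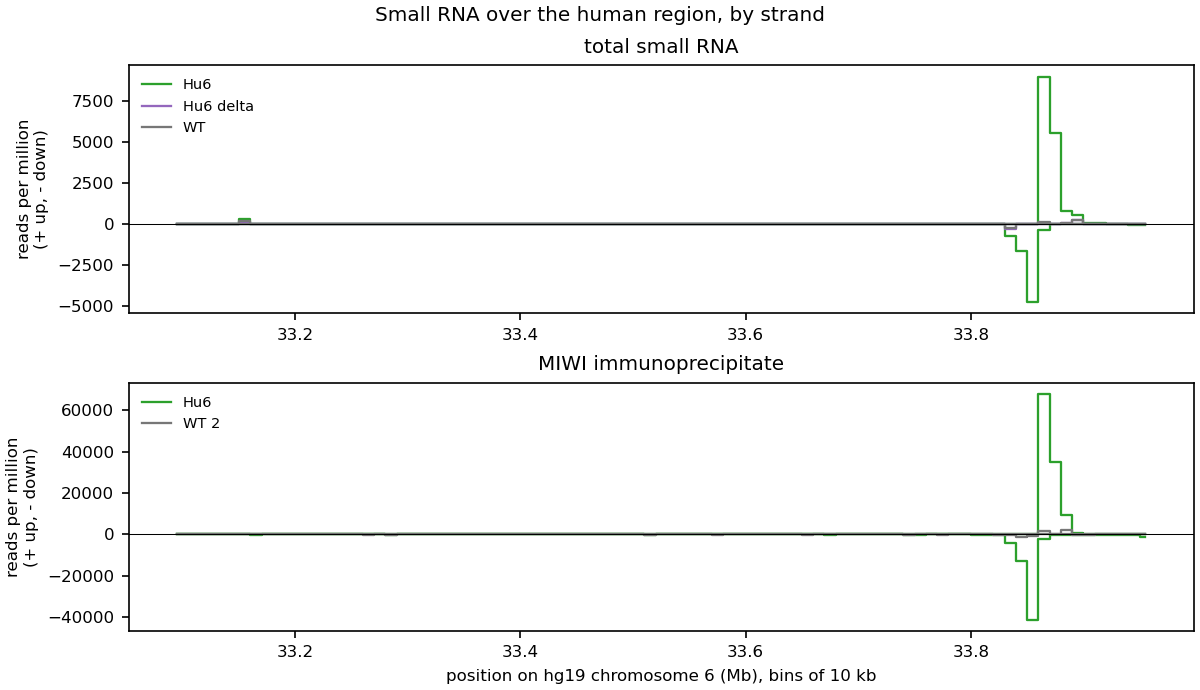
Small RNA level in RPM in bins along human chromosome 6 (hg19), plus strand upwards and minus strand downwards, for total small RNA of Hu6, Hu6 delta and WT testes and for MIWI immunoprecipitates of Hu6 and WT. The Hu6 lines rise between 33830001 and 33900000.

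Most mouse small RNA reads in the MIWI immunoprecipitates had the length of piRNAs. In WT 1, 77.99% of 75472643 reads mapped to mm9 were 24 to 33 nt long, and 86.45% of those began with T (95% Wilson interval 86.439 to 86.457). In WT 2, 75.52% of 64525054 reads were in that range, and 88.78% began with T (88.767 to 88.785). The most common length was 30 nt in both. A separate peak below that range lay at 19 nt, with 14.36% of the reads in WT 1 and 16.77% in WT 2. Among reads mapped to hg19, the share of 24 to 33 nt that began with T was 78.13% in the WT 2 immunoprecipitate, 80.32% in the Hu6 immunoprecipitate, and 89.76%, 90.12% and 89.87% in WT, Hu6 and Hu6 delta total small RNA.

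The RACE comparison asked which RNA 5′ ends depend on MIWI. In SS, a family of 8 positions with near-identical counts fell in KO by 6.68 ± 1.44 (adjusted p = 0.00171), at 72283536 and 72290803 on the plus strand of chromosome 1, at 83085016, 101466180, 101488696, 101503078 and 101519568 on the plus strand of chromosome 11, and at 101507228 on its minus strand (mm9). At 72283536, Het SS libraries had 6979 and 8751 reads and KO SS libraries 29 and 118. The same position held 10013 and 11648 reads in Het PY against 170 and 264 in KO PY, and 6009 and 9301 reads in Het RS against 372 and 18 in KO RS, and WT RS libraries had 1845 to 8461. Such a family can stem from 1 set of reads that aligned to repeated sequence, and the start of a small RNA with 159489 reads in the MIWI immunoprecipitates lay at the same place and strand. Position 75161534 on the plus strand of chromosome 18 rose in PY (1.35 ± 0.20, adjusted p = 5.03e-08) and SS (1.24 ± 0.20, adjusted p = 4.4e-07), and mitochondrial positions 70 (2.35 ± 0.17) and 1094 (2.36 ± 0.18) rose in SS. In SS, the 3 positions had 105507, 112432 and 93972 reads in KO 1 (1553168 in all) and 1640702, 4256343 and 4347076 in KO 2 (19987772 in all). They had 317903, 503472 and 502408 in Het 1 (7103003 in all) and 270162, 190894 and 187740 in Het 2 (3725857 in all). Raw counts follow library size. Position 70 stood at 236800 ± 264000 CPM in KO against 46550 ± 10900 CPM in Het, and 1094 at 237200 ± 276000 against 46170 ± 11200. The mitochondrial rises thus rested largely on KO 2. Position 75161534 stood at 105200 ± 82000 CPM in KO SS against 44630 ± 14700 CPM in Het SS, a spread that covered the difference. In RS edgeR called 0 positions, with 378 at an unadjusted p under 0.05, 13 by DESeq2 (1 higher, 12 lower) and 66 with the compared groups alone (12 higher, 54 lower). In SS the total of 11 (3 higher, 8 lower) was 45 (27 and 18) without KO 1, 28 (20 and 8) with RLE size factors, 99 (78 and 21) with DESeq2 and 0 without KO 2, which carried 43.5% mitochondrial reads. In PY the total of 1 was 0 without Het 2 or KO 2 and 2 without KO 1, and in RS the count was 9 without KO 1 and 1 without KO 2.

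Between Hu6 and WT RS, 427 RACE positions were higher and 45 lower of 12381 tested by edgeR, and 148 higher and 150 lower by DESeq2. All 427 were listed in no WT library, and 253 were listed in no other library of the series. Among them were 88252903 on the minus strand of chromosome 1, with 88479 to 277389 reads in the Hu6 libraries and none in WT, at 147646412 on the plus strand of chromosome 5 (8195 to 143027 reads), and at 62416952 on the plus strand of chromosome 11 (32315 to 62281 reads). Of the 45 lower positions, 43 were listed in no Hu6 library, such as 153574653 on the minus strand of chromosome 3 (799 to 7945 reads in WT). When the p-values were adjusted over the 7732 tested positions listed in both groups alone, none passed. The 472 calls had 231 distinct count patterns, and the total was 190, 197, 278 and 274 without WT 1, WT 2, WT 3 and WT 4 and 214 without Hu6 3.

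A PIWI protein cuts its target between the bases opposite positions 10 and 11 of the guide, so that 5′ ends of cut RNA lie 10 nt from the 5′ end of a piRNA on the other strand. In every RACE library the share of RACE positions with an opposite MIWI-bound small RNA was highest at 10 nt. It was 24.16% ± 0.653 (SD, n = 4) in WT RS against a mean of 12.29% at the other offsets from 1 to 20 nt, and 20.12% ± 1.67 (n = 3) against 10.61% in Hu6 RS. In PY it was 28.61% ± 3.96 against 16.01% in Het and 35.5% ± 0.115 against 21.54% in KO. In SS it was 26.86% ± 0.473 against 17.79% in Het and 29.77% ± 0.533 against 20.46% in KO. In RS it was 22.21% ± 1.57 against 12.62% in Het and 22.75% ± 1.83 against 14.27% in KO. At each stage both the 10 nt share and the mean of the other offsets were higher in KO than in Het on average. A lower ratio in KO therefore does not stand for a smaller 10 nt share here. The ratio of the 10 nt share to the other offsets was 1.787 in Het and 1.649 in KO of PY, 1.512 and 1.457 in SS, and 1.759 and 1.597 in RS. Averaged over stages the ratio differed by -0.118 between KO and Het (two-sided exact permutation p = 0.037 over 216 splits within stages). These splits treat the stages as independent. If libraries of the same number share an animal across stages, which the RNA-seq libraries of Het and KO leave possible, the whole comparison is 2 against 2. Within a stage the smallest p that 2 against 2 allows is 0.333 (exact permutation p = 0.333 in PY, 0.667 in SS and 0.667 in RS). The difference was -0.428 (exact permutation p = 0.00926) for positions with at least 10 RACE reads and -0.175 (exact permutation p = 0.037) for immunoprecipitate WT 1 alone, and 0.0742 (exact permutation p = 0.5) for small RNAs with 1 mouse locus. It did not pass with small RNA ends of at least 10 reads (-0.165, exact permutation p = 0.222), small RNAs of 24 to 33 nt (-0.127, exact permutation p = 0.0926), immunoprecipitate WT 2 alone (-0.1, exact permutation p = 0.102) or weighting by reads (-0.375, exact permutation p = 0.13). It no longer passed without PY Het 1 (-0.117), PY Het 2 (-0.119), PY KO 2 (-0.107), SS Het 2 (-0.105), SS KO 2 (-0.0979), RS Het 1 (-0.0928), RS Het 2 (-0.144) or RS KO 2 (-0.0787), with exact permutation p from 0.0648 to 0.157. The positions with an opposite small RNA and most Het reads were 173009608 on the minus strand of chromosome 1 (76209 Het and 71960 KO reads), which has copies at 173001994 and 172994366, 113778292 on the plus strand of chromosome 5 (41412 and 10131 reads), 23622288 on the minus strand of chromosome 13 (25789 and 7317 reads), 102262192 on the minus strand of chromosome 5 (22530 and 642 reads), 39983298 on the plus strand of chromosome 17 (22009 and 62871 reads) and 172994901 on the minus strand of chromosome 1 (18371 and 30944 reads), which has copies at 173002536 and 173010150. The opposite small RNAs there had 20, 1, 3, 3, 10 and 235 reads, and small RNAs that began at the position itself had 102830, 265, 8627, 945, 3291 and 1464. Small RNA 5′ ends on the same strand coincided with 93.76% to 98.08% of the positions in WT, Het and KO libraries and with 78.17% to 88.22% in Hu6 libraries. Most listed positions were thus starts of small RNAs themselves. The 10 nt peak, which KO libraries also had, therefore cannot be assigned to cuts by MIWI.

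**Figure D5:**
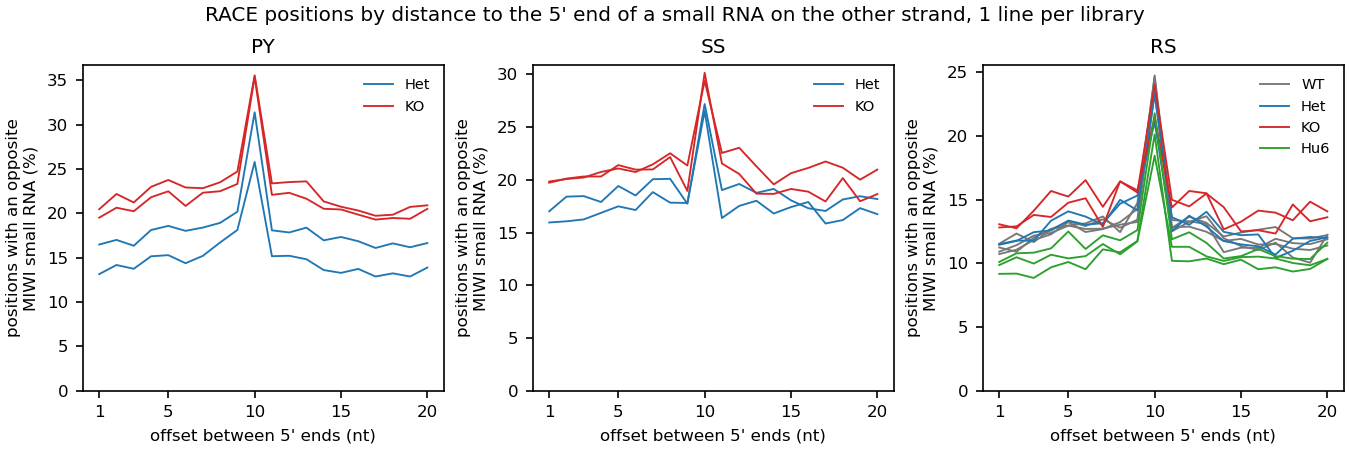
Share of RACE positions (percent) that have the 5′ end of a MIWI-bound small RNA on the other strand at each offset from 1 to 20 nt, with 1 line per library in PY, SS and RS. Each line peaks at 10 nt, at 35.5% on average in KO PY and 24.16% in WT RS.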

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

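Tests of the restriction of the Hu6 RACE lists and of that of the WT lists as the only cause, the 3 tests of ribosomal genes and the test of chance placement on chromosome 5 were chosen after the results were seen.

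The KO effect differed between RS and PY for 122 genes and between SS and PY for 20 genes by the interaction test. Differences between RS and PY passed for Tex101 (3.57), Fastkd1 (3.18), Mtg2 (2.81), Prelid1 (2.74), Ccndbp1 (2.64), Gnl2 (2.42), Morc1 (2.17), Brca2 (2.02), Ctnna2 (1.97), Rpl14 (1.95), Tdrd1 (1.78), Stambp (1.74), Antxr2 (1.70), Atr (1.65), Tmem194 (-1.28), Ptchd3 (-1.36) and Fam196b (-5.12). Differences between SS and PY passed for Tex101 (4.20), Ctnna2 (2.61), Fastkd1 (2.50), Antxr2 (1.93), Tmem194 (-1.66), Ccdc117 (-1.78), Ptchd3 (-1.83) and Fam196b (-8.33). The same difference between SS and PY had a median of 0.42 over the acrosome list (adjusted p = 0.0307, adjusted p = 0.901 with an estimated correlation) and 0.34 over the ribosomal list (adjusted p = 0.000544, adjusted p = 0.714 with an estimated correlation).

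Outside the human region of interest, the 2 windows of hg19 with the largest excess of total small RNA in Hu6 over WT were looked at, with 1 library each. Windows with a smaller excess are not given here. The window of chromosome 9 from 96000001 to 97000000 differed by 16560 RPM, and that of chromosome 21 from 17000001 to 18000000 by 15610. Both hold genes of let-7 family microRNAs, whose sequence is shared between human and mouse.

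The RACE positions higher in Hu6 than in WT were absent from the WT lists. Library size is argued against, since the 4 WT libraries held 20921615 reads in all and the Hu6 libraries 19159587. A median of 2300 reads over the 4 WT libraries was expected and 0 were seen. That expectation cannot decide by itself, since a call with 0 reads in WT required many Hu6 reads. A random division of the libraries is argued against for the count of 472, since 1 of 35 splits of the 7 libraries reached it, the real one. The highest other gave 90. The splits cannot tell a difference between mice from a difference in which positions the lists kept, since positions listed in both groups gave 0 calls. A restriction of the WT lists to small RNA ends of immunoprecipitate 1 is argued against as the only cause. Such an end held 81.5% of 27 positions of Het and KO absent from WT, against 89.3% of 187 listed there. Of the 427 called positions, 321 (75.2%) lay at such an end, between the bounds set for that test. The share was 99.4% of the 7732 tested positions listed in both groups. A restriction may therefore add to the calls and stays open. For positions missing from the Hu6 lists, a restriction to small RNA ends cannot be told apart from a difference between mice, since 16.7% of 24 absent positions lay at an end against 100% of 190 present ones. The Hu6 lists had 78.17% to 88.22% of their positions at such an end against 93.76% or more in the other lists. These shares cannot decide, since the ends were those of the WT immunoprecipitates. Small RNA ends of Hu6 on the mouse genome were not at hand.

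Ribosomal protein mRNAs were higher in Het than in WT. Depth is argued against, since the RS median was 0.96 with counts thinned to the smallest library, and so are the different gene lists, since the SS median was 1.12 where both genotypes had the same list. Library batch cannot be told apart from genotype, since every Het library differed in depth from every WT library, and the KO against Het median in RS was -0.01. Reads shared with pseudogenes, handled differently between batches, may add to it and were not tested.

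Genes on chromosome 5, which carries Piwil1, were frequent among the decreases of KO PY. Of 14 placed genes, 5 lay there (35.7% against 6.33% of genes tested), which argues against chance placement (two-sided Fisher exact p = 0.00124, adjusted p = 0.00744 over 6 tests). An allele inherited with the targeted locus would be expected to lower these genes partly in Het, and the Het against WT median in PY was -0.02. The genes split, with Antxr2 at -1.14 and 2010109A12Rik at -0.94 but Fam69a at -0.02, Fras1 at 0.37 and Afm at 2.82. Afm lay near the floor in PY, at 0.126 CPM in WT, 0.927 in Het and 0 in KO, so the size of its change is uncertain. Genotype and library batch also cannot be separated in Het against WT. Chromosome 5 held 6.07% of the decreases in SS and 5.8% in RS, where Fam69a (-0.08 and 0.05) and Fras1 (-0.18 and 0.04) did not fall. There 2010109A12Rik (-5.74 and -5.82) fell, as did the sparse Afm (-7.21 and -8.69). Antxr2 stood at -0.75 in SS (adjusted p = 0.0717) and fell in RS (-0.98, adjusted p = 0.0114). An inherited allele and an effect of MIWI therefore cannot be told apart.

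Between WT stages, 6 libraries make 10 splits, too few for a share under 0.05. The SS against PY total of 10730 was reached by 1 split, the real one, and the highest other gave 1582. The RS against SS total of 8044 was reached by 1 split, and the highest other gave 0.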

How the results depend on the processing

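Thinning, the fits without WT 2 and KO 2 of PY, 1 position per count pattern, positions listed in both groups, small RNAs with 1 mouse locus and a replicate block within Het and KO were chosen after the data were seen. Of the values under an alternative for the main results, 101 stayed within the limits set for them, 12 lost their call, 132 moved and 1 reversed. The cause was not tested unless stated. Where a library left out leaves 1 in its group, the lone sample is assumed to vary like other groups.

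With DESeq2 the counts of called genes were 144 in KO against Het PY, 1741 in SS, 1594 in Het against WT SS, 11 in Hu6, and 357 and 109 for the KO effect in RS and SS minus PY. With only the compared groups they were 69, 4905 and 6085 in KO against Het PY, SS and RS, 34 and 1609 in Het against WT PY and SS, 3 in Hu6, 6327 in SS against PY, and 864 and 118 for the KO effect in RS and SS minus PY. At FDR 0.01, a stricter threshold by construction, they were 15, 390 and 947 in KO against Het, 902, 320 and 377 in Het against WT, and 26 and 8 for the differences between stages. Thinned to the smallest library, with fewer reads, they were 22, 534 and 1284, then 1440, 397 and 309, and 53 and 6 for the differences. KO against WT gave 3768, 2692 and 5003, and KO against the mean of WT and Het 1089, 2189 and 4187. Without WT 2 and KO 2 of PY, KO against Het PY gave 72.

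The replicate numbers did not pair the WT libraries: of 9 pairs, 3 had a correlation over 0.1 (-0.42 to 0.26) and 2 matched best by number. In Het and KO, where 2 libraries give 1 value per pair of stages, all 6 pairs matched by number (0.08 to 0.24), so that libraries of the same number may share an animal or a preparation. A replicate block within Het and KO gave 70 genes for the KO effect in RS minus PY and 15 in SS minus PY. A replicate block within WT gave 6961 genes in SS against PY and 3685 in RS against SS, and a block over RACE libraries gave 165 positions in Hu6 against WT. With 1 library left out, the counts ranged from 8 to 17, 243 to 382 and 767 to 907 in KO against Het PY, SS and RS, from 335 to 3436, 241 to 1056 and 262 to 560 in Het against WT, from 3 to 6 in Hu6, from 22 to 54 and 0 to 13 for the KO effect in RS and SS minus PY, from 9144 to 11889 in SS against PY and from 6644 to 7647 in RS against SS.

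For RACE in PY, no filter gave 3 positions, DESeq2 8 (3 higher, 5 lower), only the compared groups 0 and 1 position per identical count vector 5. In SS, RLE gave 28 (20 higher, 8 lower) and DESeq2 99 (78 higher, 21 lower), against 3 higher and 8 lower. In RS, RLE gave 1, DESeq2 13 (1 higher, 12 lower), only the compared groups 66 (12 higher, 54 lower) and 1 position per identical count vector 1. In Hu6 against WT, no filter gave 183, DESeq2 298 (148 higher, 150 lower), 1 position per identical count vector 212, and positions listed in both groups 0. With 1 library left out the ranges were 0 to 2, 0 to 45, 0 to 9 and 190 to 375. Of 165 pairs of list and contrast, 55 passed with camera, 4 with an estimated correlation and 36 with fry.

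The difference in the 10 nt ratio between KO and Het passed with positions of at least 10 RACE reads (-0.428) and immunoprecipitate WT 1 alone (-0.175). It lost its call with small RNA ends of at least 10 reads (-0.165), 24 to 33 nt (-0.127), immunoprecipitate WT 2 alone (-0.1) and weighting by reads (-0.375), and reversed with 1 mouse locus (0.0742). It ranged from -0.158 to -0.0787 with 1 library left out, and lost its call without PY Het 1, Het 2 or KO 2, SS Het 2 or KO 2, or RS Het 1, Het 2 or KO 2.

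The human region held 22500 RPM in Hu6 total small RNA with 1 human locus, 181900 when scaled to reads of 24 to 33 nt and 59860 by distinct sequences. The same 3 values were 802.6, 12230 and 4052 in WT, 865.4, 14600 and 3769 in Hu6 delta, 175000, 412700 and 106000 in the Hu6 immunoprecipitate, and 5509, 38940 and 4783 in that of WT. Over distinct sequences, the share that began with T was 68.21% and 75.21% in the WT immunoprecipitates (mm9), 63.93% and 64.6% in those of WT and Hu6 (hg19), and 77.61%, 78.71% and 76.96% in total WT, Hu6 and Hu6 delta.

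Of 4478 values of named genes under an alternative, 3757 kept direction and side of the threshold, 669 lost their call in the same direction, 47 gained one and 5 reversed. KO against WT reversed Mlh3 (0.17), Khdrbs1 (0.02) and Rplp0 (0.30) in SS and Ddx6 (0.33) and Eif4e (0.30) in RS, as it replaces the control genotype. The RNA change of genes with cleavage positions and RACE counts per gene were not run, since no genome was at hand. Simulated changes of log2 1 were mostly missed (19.4% recovered in KO against Het RS). The simulation planted far fewer changes than were called in KO against Het RS and gave all genes the same spread, so recovery in the data may differ.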

Other observations

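The test of genes on the stage programme was chosen before its result was seen.

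Genes that rise and fall between stages in WT were unevenly placed in KO RS. Of the 1022 genes lower in KO RS, 606 rose from SS to RS in WT (246 expected from all genes), and 14 fell (254 expected). Of the 941 genes higher in KO RS, 289 fell from SS to RS in WT (234 expected) and 99 rose (227 expected). The shares among all genes tested, which were not matched for level in RS, were 24.1% for those that rose and 24.9% for those that fell. The WT SS libraries held more RNA of somatic markers than WT RS, as all 22 Sertoli markers (median -5.48) and 14 of 15 Leydig markers (median -6.58) fell from SS to RS in WT.

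KO round spermatids may have stopped or slowed before the spermatid programme was complete. Of the genes lower in KO RS, 59.3% were among those that rise from SS to RS in WT. This was above 1.5 times the share of all genes, the bound set for this test. However, a gene must be expressed in Het RS to be called lower in KO, which favours genes that rise into RS. Part of the excess may thus be built in, and it cannot decide. The share of genes higher in KO RS that fall at this step, 30.7%, lay between the bounds set for this test, so that transcripts kept from SS were neither shown nor excluded. Cell composition of the sorted fractions was not measured, the genes that fell in WT include somatic markers (medians of -5.48 and -6.58), and a different mix of spermatid steps in the KO fraction stays open.

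Small RNAs at the 8-position family of chromosomes 1 and 11 began at the RACE position itself, on the same strand, with 159489 reads in the MIWI immunoprecipitates. In Hu6 RS, 154 of 630 positions with at least 100 reads in each Hu6 library were listed in no other library, and 72.7% of the 154 lay at a small RNA 5′ end against 100% of the 476 others.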
